A study of Mus musculus with 12 samples.

How the data were processed

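Gene expression was measured by RNA sequencing of poly(A) RNA in 12 libraries of mouse osteoclast precursor cells, 6 kept in RANKL and 6 kept in RANKL with dexamethasone. Per the labels' protocols, marrow of femurs and tibias of male C57BL/6J mice aged 6 months was cultured, non-adherent cells were kept for 3 days in 10 ng/ml M-CSF, and differentiation was induced with 25 ng/ml RANKL and 10 ng/ml M-CSF. The protocols give a 24 h treatment, with 25 ng/ml RANKL alone or with 1e-08 M (10 nM) dexamethasone. The wording leaves open whether this period followed a first 24 h of RANKL. RNA passed a minimum integrity number before poly(A) selection and paired-end Illumina sequencing with a NEBNext Ultra kit, for which the protocols state no strand marking.

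The deposited table holds raw read counts per gene made by the authors, as whole numbers for 28293 Ensembl genes in 12 columns, one per library. Columns were matched to samples by the library names in the labels. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq 1.28.0 were used with the GRCm39 build, without roles or an order. The program that counted reads, its handling of reads with several matches and the annotation release are not given in the sources used here. Reads shared between near-identical genes, and reads from overlapping or antisense genes, therefore cannot be assigned with certainty. Coordinates are those of the deposited table. Each gene of the table had at least 1 count over the libraries, and symbols were missing or repeated for 461 genes, which are identified by Ensembl ID. Every identifier was an Ensembl gene, so no aggregate or unassigned entries entered the totals.

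Library totals ran from 16820193 counts (RANKL+Dex replicate 6) to 28523595 counts (RANKL+Dex replicate 2). Genes with few counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 13775 tested genes. Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are RANKL+Dex over RANKL, and their SE was derived from the F statistic. Levels are TMM-scaled CPM, given as mean ± SD with n = 6 per group. The design text calls the libraries biological replicates, while the extraction protocol speaks of triplicates. Whether the 6 cultures of a group came from 6 mice is not given in the sources used here, so p-values measure the spread between these cultures.

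The labels give each library a batch number from 1 to 6, shared between the groups, and a shared batch pairs the libraries by label. The numbers were checked against the data: correlations of same-numbered deviations from the group means were 0.19, 0.27, 0.05, 0.04, 0.36 and 0.08 for batches 1 to 6, with a mean of 0.165 against −0.0329 for different numbers. In 3 of 6 batches both libraries correlated best with their own number. Results come from the fit without the block. The value with batch as a block is given where it changed a call or moved a count of calls by more than 1.5 times. Each batch holds 1 library per group, so no test within a batch was possible. Chi-square statistics per gene between libraries of one group ran from 3.22 to 19.5 over 13816 genes, so no library repeated another within sampling noise.

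The following choices were made before the data were examined: the test, the threshold, 42 gene lists with 814 entries (26 of biology, 11 of other cell types and 5 of sample quality), the rule for named genes and the alternative settings. The rule named a panel of 22 genes whatever their values, and the 8 higher and 8 lower genes with the largest fold change among those past the threshold. These also needed a mean of at least 5 CPM in the higher group, the same direction in all 6 batches and a symbol that is not a clone or predicted name. From each list of biology it took up to 4 members, the 2 higher and the 2 lower with the smallest p, whether or not they passed. Naming members of both directions therefore does not show that a list was mixed, which the counts of members show. For lists of other cell types and quality it took the most abundant member and the 2 with the smallest p. A gene named outside the rule is marked as chosen after its values were seen, and some genes the rule names are not reported here.

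The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the 35 lists). Camera with an estimated correlation and fry, which tests whether the members of a list move on balance one way, were run beside it. List counts are also given after adjustment over the list alone. Depth, genes detected and shares of counts, 16 measures in all, were compared with exact two-sided permutation tests (924 arrangements, smallest possible p 0.00216) with Benjamini-Hochberg adjustment. The shares were those of mitochondrially encoded genes, ribosomal protein genes found by symbol, the 10 most abundant genes and each of 11 other-cell lists. The paired version used 64 sign flips, whose smallest possible p is 0.0312.

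The alternative settings fixed in this way were the batch block, RLE and upper-quartile factors, library size alone, no filter, a filter of 1 CPM in 6 libraries, and counts thinned to the smallest library. DESeq2 1.42.0 with and without the block, limma-voom, a robust dispersion fit, a threshold of 0.01, and leaving out each library and each batch completed them. Removal of each library's trend on transcript length and GC content was added after the data had been seen. For this check, length and GC content came from GENCODE M21 transcripts (GRCm38), joined by Ensembl ID alone, and no coordinates of that build were used.

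The test was checked on simulated counts of the same 13775 genes with 200 genes changed. All changed genes were drawn from those with a mean of at least 1 CPM. At 1.2-fold, 34.3% of 67 genes were recovered, against 83.6% of 67 at 1.5-fold and 90.9% of 66 at 2-fold. A simulated list of 25 further genes raised 1.2-fold gave 11 calls. Of all 156 calls, 6 (3.85%) were of unchanged genes. The simulated list had a camera adjusted p of 2.9e-24, and 0 of 40 unchanged lists were called. Each gene was simulated independently, whereas real lists can be correlated (estimated correlation 0.730 for ribosomal proteins). The simulated lists therefore cannot show how often such correlation gives false list calls. Changes near 1.2-fold were thus detected only in part in these simulations. Far fewer genes changed in them than the 2139 called in the data, which makes the adjusted threshold stricter. The recovered shares are therefore not those of the data. Figures were drawn with matplotlib 3.10.9.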

Results

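RNA sequencing was used to compare mouse osteoclast precursor cells exposed to dexamethasone, a synthetic glucocorticoid, with cells given the osteoclast-inducing cytokine RANKL alone. According to the protocols, the steroid was added to mimic glucocorticoid-induced osteonecrosis of the femoral head in culture. The 12 libraries fell into 2 groups of 6, RANKL (25 ng/ml, 24 h) and RANKL+Dex (the same with 10 nM dexamethasone), and each group held batches 1 to 6. Totals lay between 17674405 and 25451498 counts in RANKL and between 16820193 and 28523595 in RANKL+Dex, with 20252 to 21776 genes detected per library. Osteoclast genes were among the most abundant transcripts: Mmp9 took 2.27% of counts, Ctsk 1.54% and Acp5 0.679%.

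Dexamethasone changed the expression of 2139 of 13775 tested genes, 1099 higher and 1040 lower, and most changes were small. Classical glucocorticoid targets such as Fkbp5 and Per1 rose more than 2-fold, as did the calcitonin receptor gene Calcr, from 97.4 ± 7.90 to 272 ± 32.7 CPM (n = 6). Antigen presentation genes were lower as a list by camera (adjusted p = 0.0882 with an estimated correlation), and Cd74, the MHC class II invariant chain gene, fell from 46.0 ± 12.7 to 12.9 ± 2.17 CPM (n = 6). Genes of the unfolded protein and integrated stress response were higher as a list, and neutrophil markers were lower as a list. Core osteoclast genes changed little: Ctsk, Acp5 and Nfatc1 rose (log2 fold changes 0.20, 0.17 and 0.15) and Itgb3 fell (−0.15). The Nfatc1 and Itgb3 calls did not hold in every setting. Mmp9 and Dcstamp did not differ beyond the replicate spread by the edgeR test. The calls are those of the edgeR quasi-likelihood test at an adjusted p under 0.05, or of camera for a group.

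A change of at least 2-fold was seen in 161 genes, 68 higher and 93 lower, and the median absolute log2 fold change of the changed genes was 0.27. Among the 2139 changed genes, 1780 (83.2%) moved the same way in all 6 batches. With batch as a block edgeR called 3000 genes, 1465 higher and 1535 lower, of which 2125 were among the 2139. Leaving out 1 library gave 1626 genes (without RANKL+Dex replicate 4) to 2493 (without RANKL+Dex replicate 1), while leaving out batch 4 gave 1339 and batch 6 gave 1409. The common biological coefficient of variation was 8.67%.

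**Figure D1:**
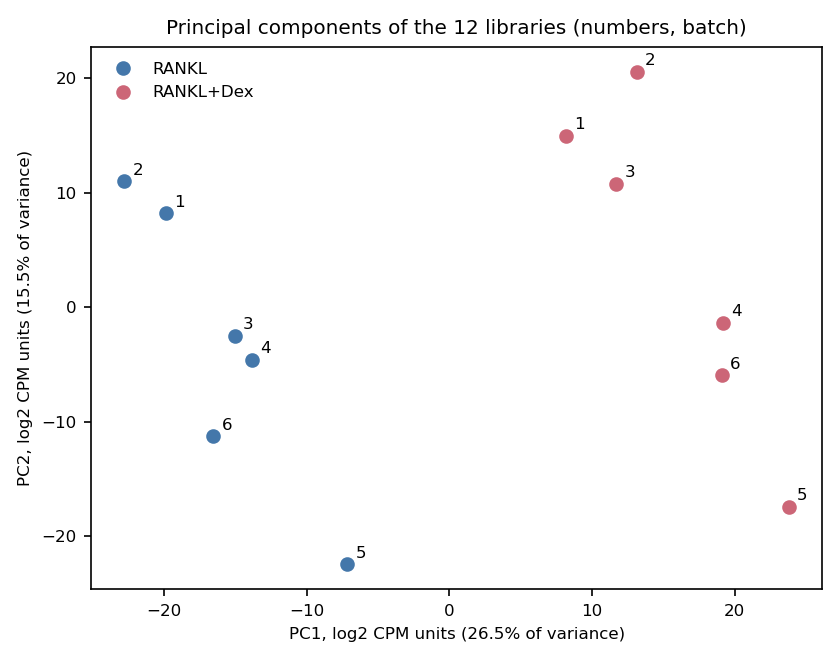
Principal components of log2 CPM, each point a library, coloured by group and numbered by batch, with PC1 (26.5% of variance) on the x axis and PC2 (15.5%) on the y axis. RANKL libraries lie between −22.8 and −7.13 on PC1 and RANKL+Dex libraries between 8.20 and 23.8.

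Glucocorticoid receptor targets were higher as a list by camera (adjusted p = 1.1e-04, with adjusted p = 0.209 with an estimated correlation), with large changes in a few members. Per1, a clock gene with glucocorticoid response elements, rose from 20.2 ± 1.16 to 52.2 ± 4.82 CPM (n = 6, log2 fold change 1.37 ± 0.06, edgeR adjusted p = 4.7e-10). Fkbp5, which encodes a co-chaperone of the receptor, rose from 15.2 ± 0.803 to 41.6 ± 6.96 CPM (1.46 ± 0.09, edgeR adjusted p = 1.4e-08), and the transcription factor gene Klf9 rose 2.61-fold (1.38 ± 0.07). Tsc22d3, which encodes the anti-inflammatory mediator GILZ, rose from 37.6 ± 2.79 to 71.6 ± 9.31 CPM (0.93 ± 0.08, edgeR adjusted p = 4.0e-07). Lcn2 fell from 2.92 to 0.952 CPM (−1.61 ± 0.25) and Rgs2 from 25.7 to 17.5 CPM (−0.55 ± 0.07). Of 25 tested members 5 rose, 3 fell and 17 did neither, or 5 higher and 4 lower when adjusted over the list alone and 8 higher and 5 lower with the block. The list's median log2 fold change was 0.04. Dusp1, which encodes a MAP kinase phosphatase, was at 28.3 ± 6.78 CPM in RANKL and 34.5 ± 8.74 CPM in RANKL+Dex (edgeR adjusted p = 0.244), and passed with the block (0.00107). Zbtb16 lay below the filter, with 9 counts over the 6 RANKL libraries and 33 over the 6 RANKL+Dex libraries (exact two-sided permutation p = 0.0195, n = 6).

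The receptor gene itself, Nr3c1, fell from 66.9 ± 3.01 to 59.0 ± 4.49 CPM (log2 fold change −0.18 ± 0.05, edgeR adjusted p = 0.0216) and was lower in 6 of 6 batches. Its call ended without RANKL replicate 2 (adjusted p = 0.0526) and without RANKL+Dex replicate 4 (0.0536) in edgeR, and after removal of the length and GC trend (0.0526). It also ended without batch 3 (0.0954), 4 (0.0655) or 6 (0.0511). In GRCm39, Fkbp5 (ENSMUSG00000024222) spans chromosome 17 from 28618068 to 28736501 on the minus strand, Per1 (ENSMUSG00000020893) chromosome 11 from 68986043 to 69000786 on the plus strand, and Calcr (ENSMUSG00000023964) chromosome 6 from 3685680 to 3764714 on the minus strand. Cd74 (ENSMUSG00000024610) spans chromosome 18 from 60936920 to 60945724 on the plus strand, and Cd55 (ENSMUSG00000026399) chromosome 1 from 130366764 to 130390481 on the minus strand.

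**Figure D2:**
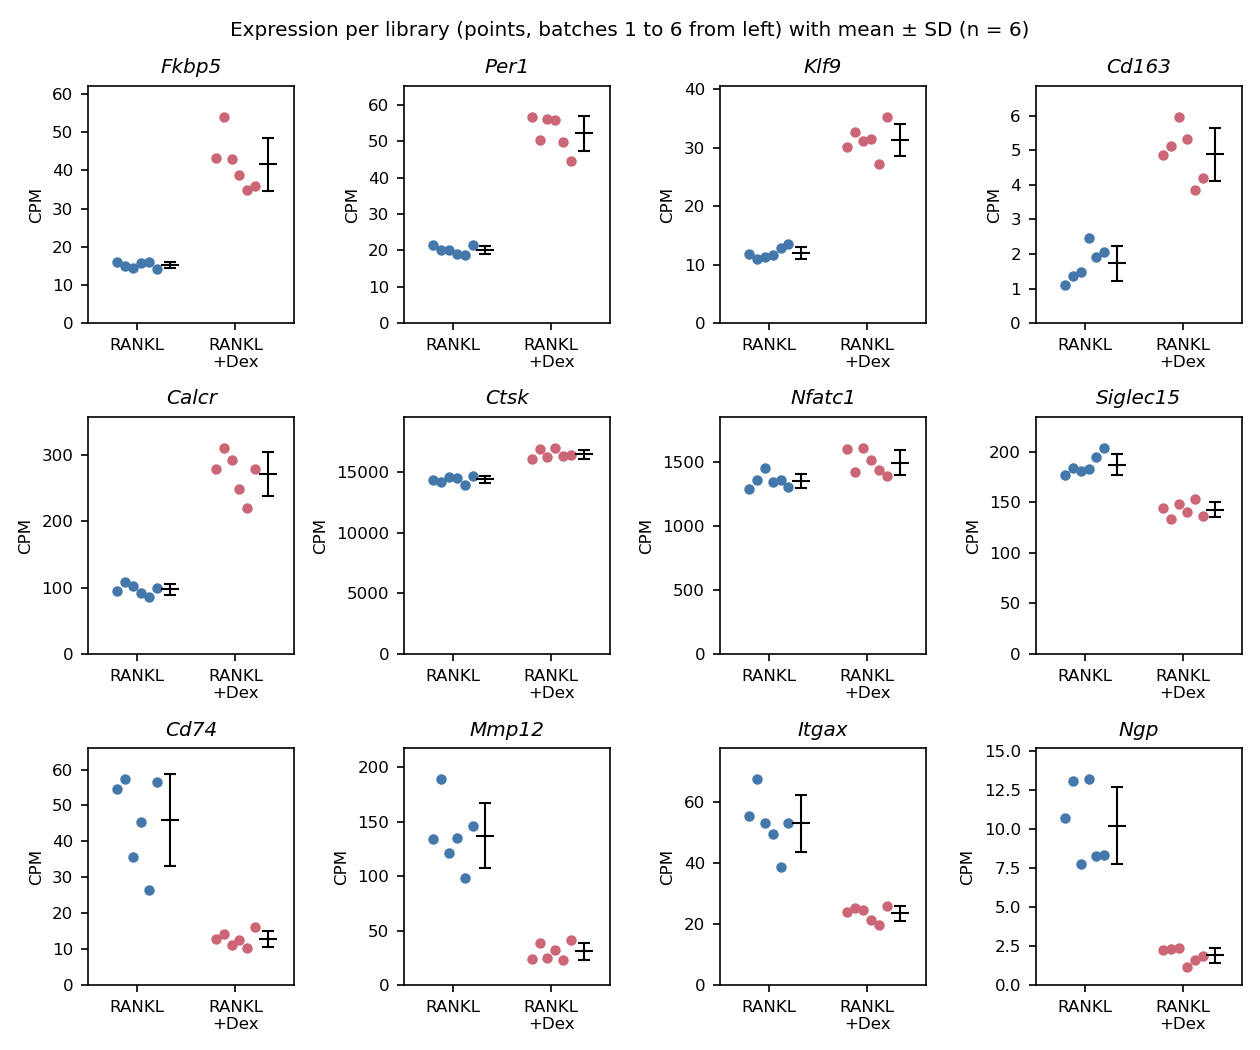
Expression in CPM (y axis, from 0) of 12 genes in each library, points ordered by batch within RANKL and RANKL+Dex, with mean ± SD (n = 6) beside each group. Calcr lies between 85.8 and 108 CPM in RANKL and between 219 and 311 in RANKL+Dex, and Cd74 between 26.4 and 57.4 in RANKL and between 10.2 and 16.2 in RANKL+Dex.

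Genes that glucocorticoids raise in macrophages were higher as a list by camera (adjusted p = 4.7e-05, with adjusted p = 0.422 with an estimated correlation). The haemoglobin scavenger receptor gene Cd163 rose from 1.73 ± 0.505 to 4.89 ± 0.772 CPM (n = 6, log2 fold change 1.51 ± 0.18, edgeR adjusted p = 1.9e-05), and C1qa, which encodes a chain of complement C1q, from 18.1 ± 3.31 to 36.9 ± 7.44 CPM (1.04 ± 0.13). The mannose receptor gene Mrc1 fell from 59.1 ± 9.69 to 46.1 ± 3.91 CPM (−0.35 ± 0.09, edgeR adjusted p = 0.0137). Among 18 tested members 10 rose, 1 fell and 7 did neither, 10 higher and 3 lower when adjusted over the list alone and 10 higher and 5 lower with the block.

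Osteoclast effector genes, which encode the machinery of bone resorption, moved in both directions. Calcr showed the largest change of the list (log2 fold change 1.48 ± 0.07, edgeR adjusted p = 1.3e-09). The collagenolytic protease gene Ctsk rose by a small margin, from 14401 ± 288 to 16497 ± 371 CPM (0.20 ± 0.03, adjusted p = 1.1e-04), as did the tartrate-resistant acid phosphatase gene Acp5, from 6405 ± 273 to 7189.8 ± 403 CPM (0.17 ± 0.04, adjusted p = 0.00930), and the proton pump subunit gene Atp6v1c1 (0.25 ± 0.03). Siglec15, which encodes a sialic acid receptor of osteoclasts, fell from 187 ± 10.1 to 142 ± 7.37 CPM (−0.39 ± 0.04, edgeR adjusted p = 9.8e-06). The integrin gene Itgb3 fell from 1157 ± 59.4 to 1042 ± 39.1 CPM (−0.15 ± 0.04, adjusted p = 0.0132), a call that ended after removal of the length and GC trend (0.0686) and without batch 4 (0.0540). Mmp9, which encodes a gelatinase, was at 23115 ± 1048 CPM in RANKL and 22258 ± 1303 CPM in RANKL+Dex (log2 fold change −0.05 ± 0.04, edgeR adjusted p = 0.418) and the fusion gene Dcstamp at 733 ± 33.2 CPM in RANKL and 725 ± 60.0 CPM in RANKL+Dex (−0.02 ± 0.05, adjusted p = 0.881). In the list, 6 rose, 3 fell and 15 did neither of 24 tested, 8 higher and 5 lower when adjusted over the list alone and 6 higher and 6 lower with the block. It was higher by camera (adjusted p = 0.0211), with adjusted p = 0.422 with an estimated correlation. The camera call ended without RANKL replicate 1 (adjusted p = 0.0537), without RANKL replicate 5 (0.0528) and without batch 1 (0.0751).

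Regulators of the osteoclast lineage had more lower than higher members. Nfatc1, which encodes the transcription factor that drives osteoclast differentiation, rose from 1354 ± 57.3 to 1498 ± 95.3 CPM (n = 6, log2 fold change 0.15 ± 0.04, edgeR adjusted p = 0.0273). That call ended in edgeR without RANKL replicate 1 (adjusted p = 0.0563), 4 (0.0545) or 6 (0.0603) and without RANKL+Dex replicate 3 (0.0650) or 4 (0.0552), as it did without batch 1 (0.0935) or 4 (0.0993). Myc fell from 74.4 ± 2.09 to 58.5 ± 6.14 CPM (−0.34 ± 0.06, edgeR adjusted p = 5.4e-04) and Pparg, which encodes a lipid-sensing nuclear receptor, from 5.26 ± 0.897 to 2.97 ± 0.550 CPM (−0.81 ± 0.15, adjusted p = 0.00106). The receptor genes Tnfrsf11a, which encodes RANK, and Csf1r, which encodes the M-CSF receptor, had log2 fold changes of 0.08 ± 0.03 and 0.04 ± 0.06 (edgeR adjusted p = 0.109 and 0.747). Of 25 members 2 rose, 7 fell and 16 did neither, 6 higher and 8 lower when adjusted over the list alone and 4 higher and 8 lower with the block. The list did not pass (camera adjusted p = 0.157), but was just called without batch 1 (0.049985).

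Negative regulators of osteoclast formation included the deubiquitinase gene Cyld, which rose (0.16 ± 0.04, edgeR adjusted p = 0.00634), and the transcriptional repressor gene Bach2, which fell (−0.53 ± 0.12, adjusted p = 0.00802). Irf8, which encodes a repressor of Nfatc1, was at 20.5 ± 5.47 CPM in RANKL and 15.2 ± 3.14 CPM in RANKL+Dex (log2 fold change −0.42 ± 0.16, edgeR adjusted p = 0.0861) and was lower in 6 of 6 batches. It passed with the block (adjusted p = 3.4e-04), without RANKL replicate 5 (0.0142) and without RANKL+Dex replicate 2 (0.0422). In all, 1 rose, 3 fell and 13 did neither of 17 tested, 2 higher and 4 lower when adjusted over the list alone and 2 higher and 7 lower with the block. Camera gave adjusted p = 0.173, against 0.0289 with the block, 0.0403 without RANKL replicate 5 and 0.0488 without RANKL+Dex replicate 2.

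Cell fusion and podosome genes, needed for the multinucleated adherent cell, fell more often than they rose. The integrin gene Itgav fell from 1248 ± 61.6 to 1068 ± 68.1 CPM (n = 6, −0.22 ± 0.04, edgeR adjusted p = 0.00239) and the tetraspanin gene Cd9 from 255 ± 19.1 to 221 ± 7.16 CPM (−0.21 ± 0.05, adjusted p = 0.00528). Of 21 members 1 rose, 6 fell and 14 did neither, 2 higher and 7 lower when adjusted over the list alone and 2 higher and 7 lower with the block, with a camera adjusted p of 0.135 and a fry adjusted p of 0.0127. Among secreted coupling and angiogenic factors, the sphingosine kinase gene Sphk1 rose from 37.0 ± 1.43 to 62.3 ± 5.45 CPM (0.75 ± 0.05, edgeR adjusted p = 1.0e-07) and the ephrin gene Efnb2 from 39.7 to 55.4 CPM (0.48 ± 0.08), whereas Tgfb1 fell from 270.1 ± 6.85 to 222 ± 6.37 CPM (−0.28 ± 0.03, adjusted p = 1.0e-05). Pdgfb, which encodes a growth factor chain secreted by preosteoclasts, was at 447 ± 13.7 CPM in RANKL and 448 ± 23.5 CPM in RANKL+Dex (0.00 ± 0.04, edgeR adjusted p = 0.968). In this list 3 rose, 3 fell and 12 did neither of 18 tested, 4 higher and 4 lower when adjusted over the list alone and 3 higher and 5 lower with the block. Its camera adjusted p was 0.388, and 0.0373 with the block.

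The 8 higher genes with the largest change were Cd55, Tmod1, F13a1, Chil3, Ms4a4a, Sema3d, Prkce and Ms4a6b. Cd55, which encodes a complement regulator, rose 17.8-fold from 0.294 ± 0.178 to 5.31 ± 0.969 CPM (n = 6, log2 fold change 4.16 ± 0.26, edgeR adjusted p = 1.6e-08). Tmod1, an actin-capping gene, rose 6.58-fold, the coagulation factor gene F13a1 5.96-fold and the chitinase-like gene Chil3 5.53-fold. Ms4a4a rose 4.37-fold, the semaphorin gene Sema3d 4.16-fold, the protein kinase C gene Prkce 4.02-fold and Ms4a6b 3.59-fold. The 8 lower genes were Ngp, H2-Aa, Mmp12, S100a9, Cd74, Serinc2, Clec7a and Egr2. Mmp12, which encodes macrophage elastase, fell from 137 ± 30.2 to 30.9 ± 7.94 CPM (log2 fold change −2.15 ± 0.16, edgeR adjusted p = 1.1e-07), and Clec7a, which encodes a receptor for fungal glucans, from 88.4 ± 34.4 to 27.8 ± 12.1 CPM (−1.64 ± 0.27, adjusted p = 5.5e-04). Serinc2 (−1.76 ± 0.23) and the transcription factor gene Egr2 (−1.64 ± 0.24) fell as well.

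**Figure D3:**
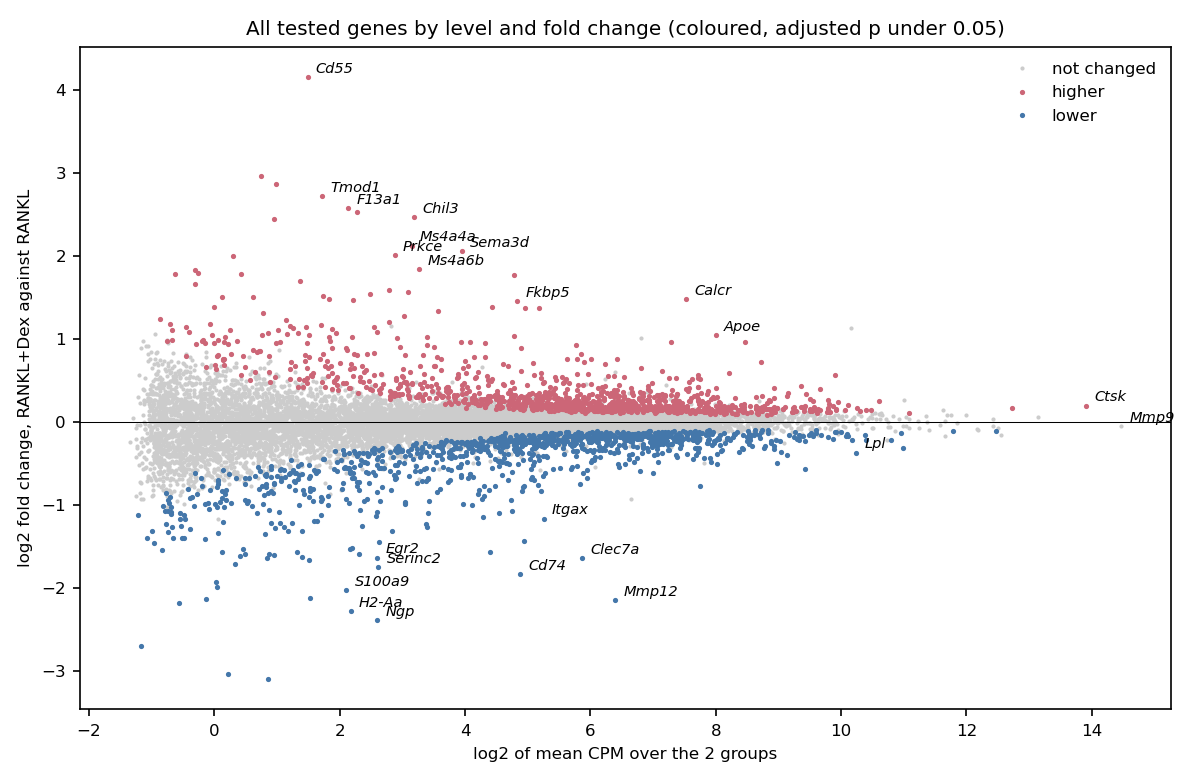
Log2 fold change of RANKL+Dex over RANKL (y axis) against log2 of the mean CPM over the 2 groups (x axis) for the 13775 tested genes. Coloured points passed the edgeR test (1099 higher, 1040 lower), and labels mark the largest changes and selected abundant genes, among them Cd55 (4.16) and Mmp9 (−0.05).

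Antigen presentation genes were lower as a list by camera (adjusted p = 2.0e-07, with adjusted p = 0.0882 with an estimated correlation), and Cd74 and H2-Aa were among the members that fell. Cd74 had a log2 fold change of −1.83 ± 0.17 (edgeR adjusted p = 1.4e-06), and the class II chain gene H2-Aa fell from 7.49 ± 2.30 to 1.55 ± 0.661 CPM (n = 6, −2.29 ± 0.25, adjusted p = 1.1e-05). Of 20 members 0 rose, 9 fell and 11 did neither, 1 higher and 11 lower when adjusted over the list alone. Chemotaxis and adhesion receptors were also lower as a list by camera (adjusted p = 1.2e-05, with adjusted p = 0.154 with an estimated correlation). The integrin gene Itgax fell from 52.8 ± 9.30 to 23.4 ± 2.36 CPM (−1.17 ± 0.10, edgeR adjusted p = 7.5e-07) and the chemokine receptor gene Ccr2 fell 2.48-fold (−1.31 ± 0.19, adjusted p = 1.5e-04). Among 20 members 0 rose, 10 fell and 10 did neither, 1 higher and 10 lower when adjusted over the list alone and 1 higher and 10 lower with the block. Beside these falls, the share of counts in neutrophil markers was lower in RANKL+Dex, at 0.00256% ± 0.000482 against 0.00617% ± 0.00143 in RANKL (n = 6, exact permutation adjusted p = 0.0173), and the shares in endothelial markers (permutation adjusted p = 0.0173) and B cell markers (0.0433) were lower as well.

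Some inflammatory genes fell, most of them from low levels. Acod1, which encodes the itaconate-producing enzyme, fell from 4.70 ± 0.878 to 1.07 ± 0.459 CPM (n = 6, −2.13 ± 0.22, edgeR adjusted p = 5.5e-06), and the interleukin-1 receptor antagonist gene Il1rn from 152 ± 17.9 to 116 ± 9.28 CPM (−0.38 ± 0.07, adjusted p = 0.00162). Tnf fell from 10.6 ± 1.14 to 8.21 ± 0.992 CPM (−0.37 ± 0.09, edgeR adjusted p = 0.0134), a call that ended without batch 4 (0.0717), and the prostaglandin synthase gene Ptges rose from 8.75 ± 1.37 to 13.9 ± 1.91 CPM (0.67 ± 0.11, adjusted p = 4.9e-04). Il1b lay below the filter, with 18 counts over the 6 RANKL libraries and 4 over the 6 RANKL+Dex libraries (exact two-sided permutation p = 0.0195, n = 6). Of 10 tested cytokines and enzymes 1 rose, 3 fell and 6 did neither, 1 higher and 3 lower when adjusted over the list alone, with camera adjusted p = 0.156 and fry adjusted p = 0.0461. For the 10 chemokines, 0 rose, 1 fell and 9 did neither, 0 higher and 1 lower when adjusted over the list alone and 0 higher and 2 lower with the block (camera adjusted p = 0.388). The abundant chemokine gene Ccl9 was at 1398 ± 42.1 CPM in RANKL and 1490.2 ± 92.6 CPM in RANKL+Dex (0.09 ± 0.04, edgeR adjusted p = 0.137, and 0.0153 without RANKL+Dex replicate 1).

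Interferon-stimulated genes were lower as a list by camera (adjusted p = 0.00147, with adjusted p = 0.422 with an estimated correlation). The antiviral genes Oas3 and Rsad2 fell from 4.03 ± 1.51 to 1.27 ± 0.313 CPM (−1.63 ± 0.24, edgeR adjusted p = 2.0e-04) and from 1.62 ± 0.576 to 0.413 ± 0.139 CPM (−1.93 ± 0.29, adjusted p = 2.3e-04; n = 6). Oasl1, a member of the same family as Oas3, rose from 2.84 ± 0.260 to 4.18 ± 0.537 CPM (0.56 ± 0.12, edgeR adjusted p = 0.00401). Of 21 tested 1 rose, 7 fell and 13 did neither, 1 higher and 8 lower when adjusted over the list alone. Under the filter of 1 CPM in 6 libraries the camera adjusted p was 0.108.

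Genes of the unfolded protein and integrated stress response were higher as a list by camera (adjusted p = 2.0e-07, and adjusted p = 0.0374 with an estimated correlation). The asparagine synthetase gene Asns rose from 75.4 ± 7.38 to 110.0 ± 8.97 CPM (n = 6, 0.54 ± 0.06, edgeR adjusted p = 2.1e-05) and Manf, which encodes a secreted endoplasmic reticulum stress factor, from 96.7 ± 3.18 to 124 ± 9.08 CPM (0.36 ± 0.05, adjusted p = 4.8e-05). Atf3, a stress-induced transcription factor gene, fell from 23.8 ± 3.79 to 13.4 ± 2.38 CPM (−0.82 ± 0.12, adjusted p = 2.0e-04). Of 24 members 11 rose, 1 fell and 12 did neither, 16 higher and 1 lower when adjusted over the list alone. Together with the neutrophil list this was 1 of 2 lists that held, out of 14 called by camera (9 higher and 5 lower) among 35, with an estimated correlation.

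Nuclear genes of oxidative phosphorylation (adjusted p = 1.2e-05, with adjusted p = 0.355 with an estimated correlation) and cytosolic ribosomal protein genes (adjusted p = 2.5e-07, with adjusted p = 0.478 with an estimated correlation) were higher as lists by camera, by small amounts. Sdhb, a succinate dehydrogenase gene, rose from 285 ± 5.74 to 324 ± 18.6 CPM (n = 6, 0.18 ± 0.04, edgeR adjusted p = 0.00326) as did the cytochrome oxidase gene Cox7a2 (0.18 ± 0.04, adjusted p = 0.00390). Of 30 oxidative phosphorylation genes 11 rose, 0 fell and 19 did neither, 15 higher and 0 lower when adjusted over the list alone. After removal of the length and GC trend 7 of these genes were higher. The 13 mitochondrially encoded genes gave 0 calls in edgeR, also when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 calls in DESeq2 and limma-voom (camera adjusted p = 0.244). With the block 2 higher and 0 lower were called, and mt-Co1 was at 8841 ± 390.2 CPM in RANKL and 9204 ± 535 CPM in RANKL+Dex (edgeR adjusted p = 0.379). Far lower were mt-Co2 (79.2 and 82.1 CPM), mt-Co3 (66.9 and 101) and mt-Atp6 (51.1 and 70.6). Their counts are uncertain because the handling of reads with several matches is not given, so the lack of edgeR calls says little about them. Of 30 ribosomal protein genes 15 rose, 0 fell and 15 did neither, 22 higher and 0 lower when adjusted over the list alone, with a median log2 fold change of 0.14. After removal of the trend 7 of these were higher. Rpl10 rose (log2 fold change 0.15 ± 0.03, edgeR adjusted p = 0.00306), and had 0.07 after that removal (adjusted p = 0.0992).

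Lysosomal genes rose in part: the glycosidase gene Gusb rose from 806 ± 18.7 to 967 ± 30.8 CPM (n = 6, log2 fold change 0.26 ± 0.03, edgeR adjusted p = 1.8e-05). Of 27 members 8 rose, 2 fell and 17 did neither, 10 higher and 2 lower when adjusted over the list alone and 9 higher and 4 lower with the block. The camera adjusted p was 0.00690, with adjusted p = 0.529 with an estimated correlation and 0.0603 without RANKL replicate 5, and the fry adjusted p was 0.0532. In cholesterol synthesis, the mevalonate pathway gene Pmvk rose 1.36-fold (0.44 ± 0.06, edgeR adjusted p = 7.9e-05), and 2 rose, 0 fell and 22 did neither of 24 members, 2 higher and 0 lower when adjusted over the list alone and 6 higher and 1 lower with the block. Camera gave adjusted p = 0.0303, with adjusted p = 0.600 with an estimated correlation, and fry gave adjusted p = 0.105. The camera call ended without RANKL replicate 3 (0.0703) or 5 (0.102) and without RANKL+Dex replicate 1 (0.0797) or 2 (0.0597). Heat shock genes were called higher (camera adjusted p = 0.0304, with adjusted p = 0.204 with an estimated correlation, and 0.0597 without RANKL+Dex replicate 2). The call also ended under the filter of 1 CPM in 6 libraries (0.109) and with counts thinned to the smallest library (0.0866). Of 11 heat shock members 2 rose, 0 fell and 9 did neither, 2 higher and 0 lower when adjusted over the list alone, and the chaperonin gene Hspe1 rose by 0.29 ± 0.06 on the log2 scale (edgeR adjusted p = 0.00308).

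**Figure D4:**
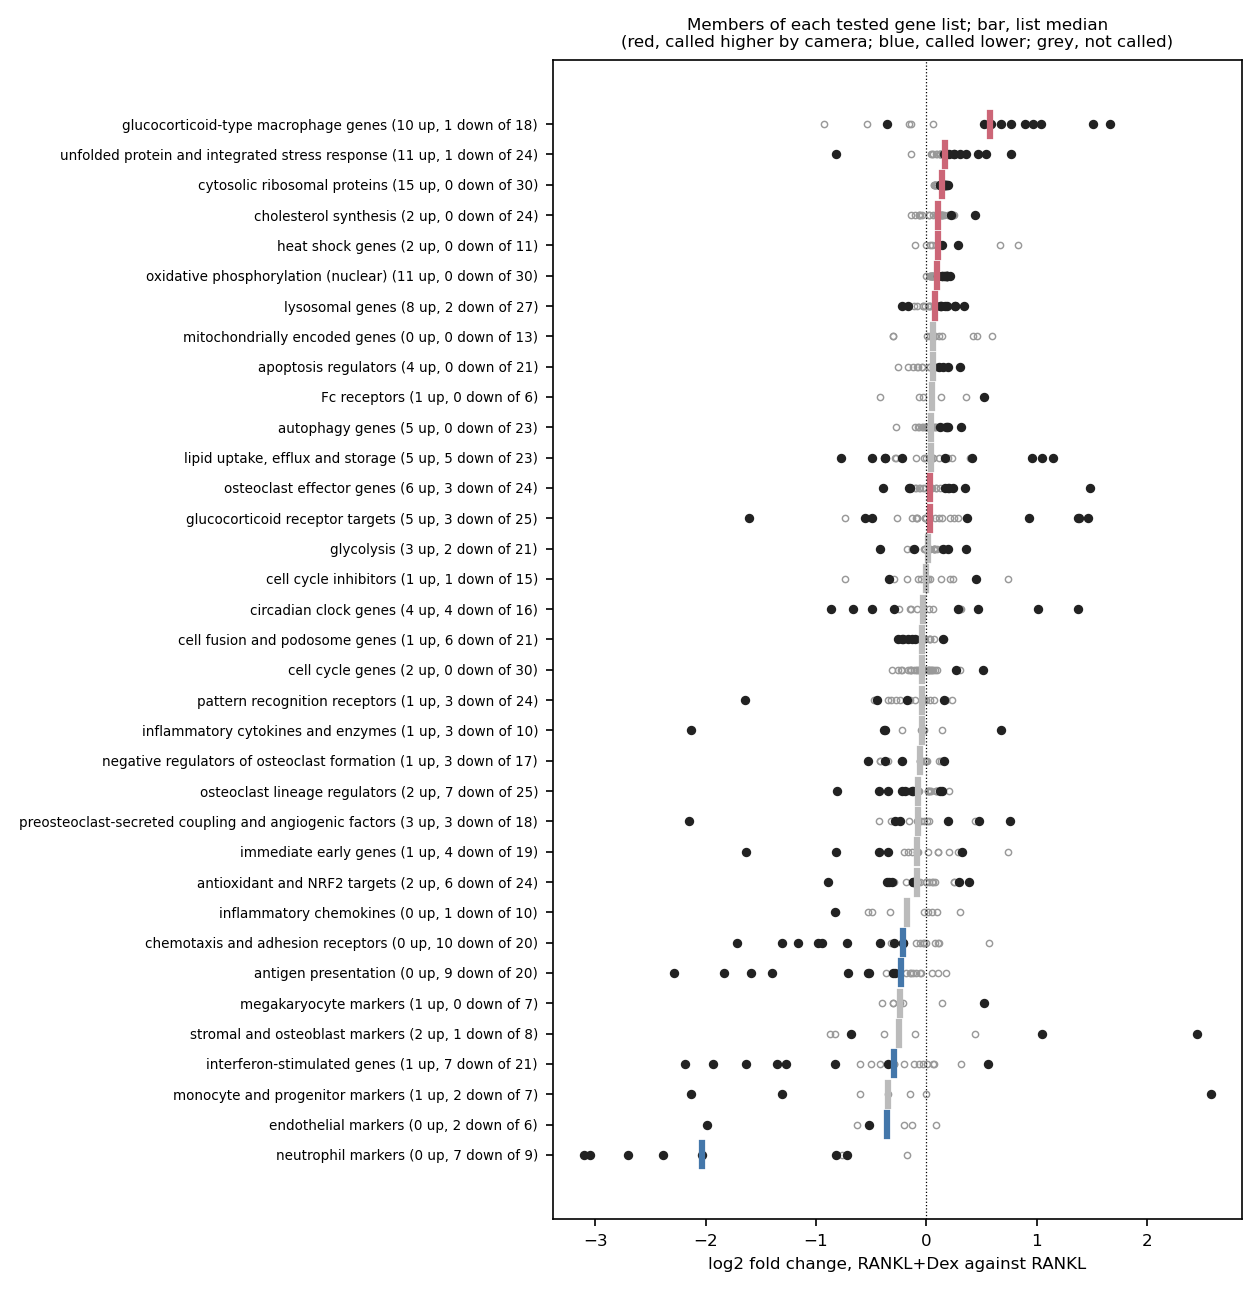
Log2 fold change of RANKL+Dex over RANKL (x axis) for each tested member of the 35 lists (filled points passed the edgeR test, open points did not), with each list's median as a bar coloured by its camera call. The neutrophil list has the lowest median (−2.03) and the glucocorticoid-type macrophage list the highest (0.58).

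Markers of other marrow cells were rare in every library, and some moved with dexamethasone. Of 9 tested neutrophil markers 0 rose, 7 fell and 2 did neither, 0 higher and 8 lower when adjusted over the list alone. Ngp, a granule protein gene, fell from 10.2 ± 2.49 to 1.91 ± 0.487 CPM (n = 6, −2.39 ± 0.18, edgeR adjusted p = 1.8e-07), as did S100a9 (−2.03 ± 0.17) and Mmp8, the most abundant member (−0.82 ± 0.18). Camera gave adjusted p = 2.3e-19, and 0.0145 with an estimated correlation. Endothelial markers were lower (camera adjusted p = 0.00180, with adjusted p = 0.134 with an estimated correlation): of 6, 0 rose, 2 fell and 4 did neither, 0 higher and 2 lower when adjusted over the list alone, and Vwf, which encodes von Willebrand factor, fell (−0.52 ± 0.08, edgeR adjusted p = 1.9e-04), as did Kdr, from 1.64 to 0.413 CPM. Among 7 monocyte and progenitor markers 1 rose, 2 fell and 4 did neither, 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.229). For 7 megakaryocyte markers, 1 rose, 0 fell and 6 did neither, 1 higher and 0 lower when adjusted over the list alone and 1 higher and 2 lower with the block (camera adjusted p = 0.970). Stromal and osteoblast markers split, as 2 rose, 1 fell and 5 did neither of 8, 2 higher and 1 lower when adjusted over the list alone and 2 higher and 2 lower with the block, with a median log2 fold change of −0.24 and a mean of 0.13 (camera adjusted p = 0.701). The proteoglycan gene Dcn rose from 0.601 ± 0.177 to 3.25 ± 1.03 CPM (edgeR adjusted p = 4.2e-06) and Runx2, which encodes an osteoblast transcription factor, fell from 5.69 to 3.53 CPM.

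Lists with fewer than 5 tested members had no set test. The 1 tested B cell marker, Ighm, was at 2.65 ± 0.222 CPM in RANKL and 1.97 ± 0.493 CPM in RANKL+Dex (n = 6, edgeR adjusted p = 0.0721, and 0.0202 without RANKL+Dex replicate 4). It was lower in limma-voom (adjusted p = 0.0452) and when adjusted over the list alone, which for 1 member is the unadjusted p. Of 4 T and NK cell markers 0 rose, 0 fell and 4 did neither in edgeR, with 3 at an unadjusted p under 0.05 and 1 call in DESeq2, 0 higher and 3 lower when adjusted over the list alone and 0 higher and 3 lower with the block. The 1 tested mast cell and basophil marker, Gata2, rose from 0.786 ± 0.284 to 1.55 ± 0.373 CPM (edgeR adjusted p = 0.0151). Adjusted over the list alone, again the unadjusted p, it rose as well. The 4 dendritic cell markers (median log2 fold change −0.05, mean 0.04) and the adipocyte marker Lipe gave 0 calls in edgeR, also when adjusted over the list alone, 0 in DESeq2 and 0 in limma-voom. At an unadjusted p under 0.05 there was 1 dendritic cell marker, and 0 erythroid markers passed the filter. Of 4 histone genes 2 rose, 0 fell and 2 did neither, 3 higher and 0 lower when adjusted over the list alone, with H1f2 rising by 0.35 ± 0.05 (edgeR adjusted p = 1.6e-04).

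As shares of all counts, 4 of 16 library measures differed by exact permutation after adjustment (n = 6 per group). These were neutrophil markers, endothelial markers (0.00664% in RANKL and 0.00497% in RANKL+Dex, adjusted p = 0.0173), B cell markers (0.000351% and 0.000255%, adjusted p = 0.0433) and mast cell markers (0.000102% and 0.000169%, adjusted p = 0.0433). The neutrophil, endothelial and B cell shares were higher in RANKL+Dex in 0 of 6 batches and the mast cell share in 6 of 6. Most of the mast cell share came from Gata2, the only tested member, and the rest of that share was not higher in RANKL+Dex. The mast cell share therefore repeats the Gata2 call and does not show a rise of these markers as a group. By paired sign flips 0 measures passed after adjustment (smallest adjusted p 0.0833), with 6 at the smallest possible unadjusted p of 0.0312. Over the tested genes alone the B cell share did not pass (adjusted p = 0.0568). Mitochondrially encoded genes held 2.29% of counts in RANKL and 2.39% in RANKL+Dex (permutation adjusted p = 0.398), and the totals did not differ by the exact permutation test (adjusted p = 0.933).

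Proliferation genes gave few calls. Mki67, a marker of cycling cells, was at 122 ± 17.4 CPM in RANKL and 105 ± 18.9 CPM in RANKL+Dex (n = 6, log2 fold change −0.22 ± 0.10, edgeR adjusted p = 0.171) and passed with the block (0.00814) and without RANKL+Dex replicate 5 (0.0130), the highest library of its group. Of 30 cell cycle genes 2 rose, 0 fell and 28 did neither, 0 higher and 0 lower when adjusted over the list alone and 3 higher and 3 lower with the block. The list did not pass (camera adjusted p = 0.756), but was called without RANKL+Dex replicate 5 (0.0428).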

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

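The neutrophil, dendritic cell and B cell tests below, the choice of granule genes and the interval required of the trend test were made only after the results they measure had been seen.

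The count of changed genes was compared with other groupings of the same libraries. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 1 gave as many genes as the real 2139, and the highest of the others gave 17. With batch as a block, 1 of 32 exchanges of libraries within batches gave as many as the real 3000, and the highest of the others gave 28. A count as high was thus rare among the groupings, at the smallest share that either comparison could give, which does not exclude chance. The other groupings mix libraries of both treatments, so a treatment effect widens their spread and lowers their counts. Of the other drawn splits 4 parted all 6 batches as the real one does.

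The neutrophil markers, 15 genes of which 0 stand in another list, were lower by unequal amounts: Mmp8 went from 3351 to 1897 counts over the group, Ngp from 1291 to 242 and S100a8 from 789 to 470. Over 13 measured members the log2 fold changes ran from −0.18 for Csf3r, −0.72 for S100a8 and −0.82 for Mmp8 to −3.10 for Ltf and −4.52 for Fcnb, and a chi-square test of heterogeneity across genes, which are not independent, excluded 1 common factor (p = 9.7e-41). This leaves fewer residual neutrophils open for all members, since expression of a member in the precursors themselves can hide part of a loss. For the 6 granule genes Ngp, Camp, Ltf, Mpo, Elane and Prtn3 the same chi-square test gave p = 0.217, with a common log2 fold change of −2.63 (95% interval −2.86 to −2.41), but 0.0484 once Fcnb (41 counts in RANKL, 1 in RANKL+Dex) was added. For these granule genes a smaller number of neutrophils or their precursors cannot be told apart from lower expression, since the answer turns on a gene with few counts, and an untested effect of dexamethasone on transcription stays open for all members.

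The class II genes Cd74 and H2-Aa fell by 1.83 and 2.29 on the log2 scale, and cells rich in class II were weighed as a source. As the whole cause, their loss requires markers that only such cells express to fall at least as far as Cd74. The counts of 11 measured B cell markers, of which 0 stand in another list, fell from 447 in RANKL to 310 in RANKL+Dex, and those of Cd79a and Cd79b from 62 to 32. Per 100 Cd74 counts the B cell markers rose from 8.10 ± 2.31 to 20.04 ± 3.29 (SD, n = 6, ratio 2.47, exact permutation adjusted p = 0.00260 over 6 marker sets). The ratio was 2.43 without Ighm and 1.85 for Cd79a and Cd79b alone (exact permutation adjusted p = 0.00260 and 0.0152). The counts of 11 dendritic cell markers, of which 3 stand in another list, were 3559 in RANKL and 3504 in RANKL+Dex. Those of Itgax went from 6626 to 2894, a fall of 1.17 on the log2 scale. Per 100 Cd74 counts the dendritic cell markers rose from 66.4 ± 24.1 to 226 ± 31.9 (ratio 3.40), and from 22.0 to 72.7 without Bst2. Itgax rose from 120 to 185 per 100 Cd74 counts (exact permutation adjusted p = 0.00260 for each). These values show only that the markers fell less than Cd74, which was chosen for its fall, so that any such marker gives a ratio above 1. Expression of a marker in the precursors can hide part of a loss, as for the neutrophil markers. Fewer B cells and fewer dendritic cells therefore stay open, as the whole cause or as part of it. Fewer class II-bearing macrophages were not tested, and lower class II expression in the precursors under dexamethasone is a hypothesis.

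The ribosomal protein and oxidative phosphorylation lists, whose transcripts are short (median 1139.5 and 1679 bases against 3138 for tested genes), were higher by small amounts. With each library's trend on length and GC removed and batch as a block, the ribosomal median was 0.103, against 0.134 with the block alone. The oxidative phosphorylation median was 0.0665 against 0.0961. Their 95% rank intervals over the member genes were 0.0875 to 0.116 and 0.0506 to 0.124. The bounds were 0.0686 and 0.0485, set from the medians without the block, 0.137 and 0.0970. These intervals treat the genes as independent, whereas their estimated correlations were 0.730 and 0.235, so the intervals are too narrow. Both medians stayed above their bounds, and both lists still passed camera with the preset correlation (adjusted p = 9.1e-05 and 0.00483). Part of each shift went with the trend: without the block, higher genes dropped from 15 to 7 and from 11 to 7. Because the genes are correlated, this cannot decide whether the trend was the whole cause. Under the other scalings the medians stayed at or above 0.126 and 0.0852. These scalings moved the median of all tested genes only between −0.00218 (RLE) and −0.0156 (library size alone). They could not have brought a list down to its bound, so this check cannot decide on scaling as the cause. Neither list held with an estimated correlation, and an effect of dexamethasone on these genes stays a hypothesis.

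A library stood apart from the other 5 of its group in 17 of 350 groups examined, against 17.5 when chance sets 1 in 20 apart. In RANKL+Dex, replicate 2 stood apart in the share of monocyte and progenitor markers (0.0113%), in F13a1 (9.47 CPM) and in Lyn (179 CPM). Replicate 5 of RANKL+Dex did so in Mki67 (141 CPM), Cd55 (3.44 CPM) and Plk1 (24.2 CPM). In RANKL, replicate 1 stood apart in Il18 (0.854 CPM) and Fos (323 CPM), replicate 2 in Slc16a3 (54.4 CPM) and replicate 3 in Xcr1 (0.834 CPM). Replicate 4 of RANKL did so in F13a1 (2.63 CPM), Ccr2 (5.36 CPM) and Rpl10 (761 CPM), replicate 5 in Rrm2 (26.7 CPM), Tfeb (39.6 CPM) and Atf3 (16.4 CPM), and replicate 6 in Nod2 (3.61 CPM).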

How the results depend on the processing

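Removal of the length and GC trend was the only setting chosen after the data had been seen. No result turned its direction under any setting, where direction was compared only for results called by either fit. The count of changed genes, 2139, moved furthest at an adjusted p under 0.01 (1002) and, among losses of libraries, ran from 1339 (without batch 4) and 1409 (without batch 6) to 2493 (without RANKL+Dex replicate 1). It was 3000 with the batch block, 2003 with the trend removed and 3121 with both, and otherwise 1915 (no filter) to 2441 (DESeq2). Of changed genes 51.4% were higher, against 43.5% with library size alone and 57.9% with the trend removed. Genes changed at least 2-fold went from 161 to 121 with the stricter filter, 166 with the block, 212 in DESeq2 and 241 without a filter.

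Of the 14 lists called by camera, 2 held with an estimated correlation. By fry 16 lists passed, which ended cholesterol synthesis (adjusted p = 0.105) and lysosomal genes (0.0532) and added 4. With the block 18 lists passed, and losses of libraries gave 13 to 16. Without a filter 21 passed, but all 42 lists then had enough members to be tested, so this count is not over the same 35. RLE, upper-quartile, library-size and trend settings without the block changed 0 of 35 list calls, while trend removal with the block added 4 and ended heat shock (adjusted p = 0.0651). Without a filter, and not in the main test, camera called cytokines (adjusted p = 0.0434), lineage regulators (0.0405), negative regulators (0.0362) and monocyte markers (0.0294). The stricter filter also called cytokines (0.0361). Cholesterol synthesis ended without batch 1 (0.0576) or 4 (0.0538), and heat shock without batch 2 (0.0766) or 6 (0.0569). The causes were not tested. Of 157 tested named genes the block ended 0 calls and added 20, and it changed no list call beyond the 4 it added. Of 16 library measures 4 passed, against 0 with paired sign flips in the replicate block, where 64 flips allow no smaller p, and 0 (without batch 2, 3 or 5) to 3 (without batch 1, 4 or 6), where 5 libraries against 5 allow no p under 0.00794, which 3 measures must reach to pass, so that these losses say little about stability. With counts thinned to the smallest library 2046 genes were called. Of simulated 1.2-fold changes 34.3% were recovered, but with far fewer genes changed than were called in the data, so this is not the recovery in the data.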

Other observations

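The genes of the last paragraph were chosen after their values had been seen, while the list tests of this part were not.

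Clock genes moved in opposite directions. Per2, which encodes a repressor of the clock, rose from 5.02 ± 0.517 to 10.1 ± 2.46 CPM (n = 6, log2 fold change 1.01 ± 0.14, edgeR adjusted p = 1.2e-04), like Per1, whereas the repressor genes Bhlhe41 (−0.87 ± 0.11, adjusted p = 3.8e-05) and Nr1d1 (−0.66 ± 0.10, adjusted p = 2.1e-04) fell. Of 16 members 4 rose, 4 fell and 8 did neither, 6 higher and 4 lower when adjusted over the list alone, with a median log2 fold change of −0.03 and a mean of 0.06 (camera adjusted p = 0.244). Genes of lipid handling also split: Apoe, which encodes a lipid carrier, rose from 167 ± 20.2 to 345 ± 101 CPM (1.05 ± 0.15, edgeR adjusted p = 1.2e-04) and the desaturase gene Scd2 from 106 ± 15.2 to 205 ± 31.0 CPM (0.96 ± 0.10), while the lipase gene Lpl (−0.37 ± 0.04, adjusted p = 1.1e-05) and Cpt1a, which encodes an enzyme of fatty acid import into mitochondria, fell (−0.38 ± 0.05, adjusted p = 1.3e-04). Of 23 members 5 rose, 5 fell and 13 did neither, 7 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.817). Among antioxidant and NRF2 targets, Nqo1, a quinone reductase gene, fell from 25.7 ± 5.79 to 13.8 ± 2.83 CPM (−0.89 ± 0.15, edgeR adjusted p = 5.0e-04) and the glutathione reductase gene Gsr rose (0.29 ± 0.04, adjusted p = 1.0e-04). There 2 rose, 6 fell and 16 did neither of 24, 2 higher and 7 lower when adjusted over the list alone and 4 higher and 9 lower with the block. Camera gave adjusted p = 0.156, 0.0428 with the block, 0.0172 without RANKL replicate 5, 0.0215 without RANKL+Dex replicate 2 and 0.0358 without a filter.

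Among pattern recognition receptors and their adaptors the kinase gene Irak1 fell (log2 fold change −0.18 ± 0.03, edgeR adjusted p = 0.00166), and 1 rose, 3 fell and 20 did neither of 24, 1 higher and 3 lower when adjusted over the list alone and 1 higher and 5 lower with the block (camera adjusted p = 0.231, and 0.00952 with the block). The neonatal Fc receptor gene Fcgrt rose from 40.2 ± 5.58 to 57.5 ± 9.41 CPM (n = 6, edgeR adjusted p = 0.00225), the only call among 6 Fc receptors (1 higher and 0 lower when adjusted over the list alone, 2 higher and 0 lower with the block, camera adjusted p = 0.624). Autophagy genes gave 5 higher and 0 lower when adjusted over the list alone, as over all genes (23 members), and the mitophagy receptor gene Bnip3l rose (0.31 ± 0.04, edgeR adjusted p = 2.2e-05). The autophagy list had camera adjusted p = 0.0811, 0.0490 without RANKL+Dex replicate 5 and 0.0240 without a filter, and fry adjusted p = 0.00513. Of 21 apoptosis regulators 4 rose, 0 fell and 17 did neither, 4 higher and 1 lower when adjusted over the list alone and 5 higher and 1 lower with the block, with the BH3-only gene Bid rising (0.30 ± 0.05, edgeR adjusted p = 7.0e-04; camera adjusted p = 0.175, fry 0.00402). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 50.0 ± 3.74 to 68.2 ± 8.45 CPM (0.45 ± 0.07, edgeR adjusted p = 5.8e-04), while of 15 such inhibitors 1 rose, 1 fell and 13 did neither, 3 higher and 1 lower when adjusted over the list alone and 4 higher and 2 lower with the block, with a median log2 fold change just below 0 and a mean of 0.01 (camera adjusted p = 0.756). The lactate exporter gene Slc16a3 fell (−0.42 ± 0.06, edgeR adjusted p = 2.7e-04) and Pfkp, a phosphofructokinase gene, rose (0.19 ± 0.04, adjusted p = 0.00197) in glycolysis, where 3 rose, 2 fell and 16 did neither of 21, 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.756). Of 19 immediate early genes 1 rose, 4 fell and 14 did neither, 2 higher and 4 lower when adjusted over the list alone and 4 higher and 4 lower with the block, and Jund, an AP-1 gene, rose (0.32 ± 0.03, edgeR adjusted p = 6.7e-06; camera adjusted p = 0.231).

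Some genes with many near-identical copies had low counts for transcripts of their kind, and their values are uncertain because the handling of reads with several matches is not given in the sources used here. Gapdh was at 25.9 CPM in RANKL and 22.9 in RANKL+Dex, beside 836 and 928 for Pgk1 of the same pathway. The mitochondrial genes mt-Co2 (79.2 and 82.1 CPM), mt-Co3 (66.9 and 101) and mt-Atp6 (51.1 and 70.6) lay far below mt-Co1 (8841 and 9204). Fdps was at 2.01 and 1.91 CPM.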
